A study of Penicillium oxalicum with 6 samples.

How the data were processed

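Messenger RNA from mycelium of Penicillium oxalicum was sequenced in 6 libraries, 3 from the parental strain and 3 from the strain in which one gene, written POc04478 in the labels, was silenced. Per the labels' protocols, poly(A) RNA was enriched with oligo(dT) beads, fragmented, reverse transcribed with random primers and made into circularised single-stranded DNA libraries. The labels state no strand-specific step. The submitters' processing notes name bcl2fastq and HISAT2, without versions or roles. The counting program, the genome build and the annotation are not given in the sources used here.

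Each deposited file holds 1 library as FPKM values, fragments scaled by transcript length and library size, which the authors computed before deposit, per the file headers. These values are already divided by library size, so a strong change in a few abundant transcripts moves the values of all others in that library. Each file lists the same 10899 IDs, of which 9822 are locus tags and 1077 are IDs of another kind without a locus tag. In parental replicate 2 the locus tags carried a prefix, which was removed before the files were joined. Of the locus tags, 9718 matched the RefSeq gene table of assembly ASM172317v3 (strain HP7-1), and 104 did not. That table gives no gene symbols beyond the locus tags and no product names, and the files give none either. The 25 gene lists that had been fixed by product name before the data were examined therefore could not be filled, and no function is assigned to any gene here. Because no build is named for the files, the table served only to name the chromosome of a gene and the order of neighbouring genes, and no coordinates are printed. The locus tags of the 246 ribosomal and transfer RNA genes of the table are not among the IDs of the files. The IDs without a locus tag were not matched to the table, so whether any of them is such an RNA is not known.

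The files give no counts, so the number of fragments per library is unknown. Relative depth was estimated from low values, because FPKM made from whole fragments falls on steps that scale with depth. Ratios between libraries were taken over genes listed between 0.15 and 1.2 FPKM in both, and the set of 6 relative depths that placed most ratios within 0.03 (log2) of the fitted ratio was kept. Over the 15 pairs of libraries, 458 of 5378 ratios lay there, while the same search reached at most 236 in 50 sets of values that had been smeared by a random factor of up to 0.25 (log2) either way, which removes the steps. With parental replicate 1 set to 1, the estimates were 1.44 and 1.16 for parental replicates 2 and 3, and 1.05, 1.58 and 1.34 for silenced replicates 1, 2 and 3. Deeper libraries give low genes less counting error, which FPKM does not show.

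The comparison, silenced against parental, was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend, no block and both groups in one fit. IDs with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 9341 IDs (8468 locus tags and 873 IDs without a locus tag). P-values were two-sided and adjusted by the Benjamini-Hochberg method, and an ID was called changed at an adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, so group means of FPKM are given beside them. The target gene was also tested with an exact permutation test, which for 3 against 3 libraries cannot give a p below 0.1. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries held the same values.

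In the absence of product names, the rule fixed before the data were examined named the target gene and, in each direction, the 2 IDs with the largest log2 fold change. These had to pass the threshold, to have a mean of at least 10 FPKM in the higher group and to have groups that did not overlap. One of the 2 selected decreases is an ID without a locus tag, and IDs of that kind are described here without printing their identifiers. Every other ID named in the text was chosen after its values were seen. Classes by abundance used the mean over all 6 libraries. Runs of neighbouring genes were defined after the data were seen, as 4 or more consecutive tested genes of a chromosome, all called in one direction with a log2 fold change of at least 1. Their number was compared with 1000 shuffles of the tested genes' order.

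The fit was tested on simulated data made from the means and within-group spread of these libraries for the silenced against parental comparison. Among 9348 simulated IDs that passed the filter, with 200 changed genes planted, 12.5% of changes of 1.5-fold, 58.3% of 2-fold, 85.7% of 4-fold and 95.9% of 8-fold were recovered, with 6 false calls among 129. With no planted change there was 1 call. The simulated noise was drawn separately for each ID, with the same spread in both groups. The false calls therefore do not carry over to real libraries in which many IDs deviate together. The adjusted threshold is stricter where few genes change, as in these simulated data, so the shares recovered do not give the power of the reported comparison. The run finder recovered 10 of 10 planted runs. These were written directly into the calls with uncalled genes at both ends, so this checks only the counting and not the power to find real runs.

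Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means, which was 0.0014 for number 1, 0.029 for number 2 and 0.12 for number 3. Parental replicates 1 and 2 correlated higher with a silenced library of another number (0.021 and 0.13). The numbers thus gave no clear sign of pairing over all tested IDs. The 3 same-numbered values were all above 0, and so few libraries cannot exclude pairing. Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, a replicate block, no variance trend, library weights and leaving out each library in turn. The search on smeared values and the folds of group means without a single library were added after the data were seen. The planned count-based tools were not run because the files hold no counts.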

Results

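The series measured transcript levels in mycelium of Penicillium oxalicum, a filamentous fungus that secretes enzymes degrading plant polysaccharides. Spores were grown in glucose medium for 24 h and the mycelium was moved for 24 h to an enzyme-production medium. The protocol and the design text name Avicel, a microcrystalline cellulose, as the sole carbon source, whereas the treatment field of every sample names raw starch, so the carbon source is not settled by the labels. The 3 parental libraries came from the strain lacking PoxKu70, a gene whose product acts in non-homologous end joining, although their genotype field reads wild type. The 3 silenced libraries came from the strain in which POc04478 was silenced after addition of 5 μM copper ions. The labels do not say whether the parental cultures received copper. The comparison asks how silencing this gene, with copper added, changed the transcriptome under enzyme-producing conditions.

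Between 9737 and 9937 of the 10899 listed IDs had a value above 0 in each library. Libraries of one group resembled each other more than libraries of different groups. Across the 9341 tested IDs, the Pearson correlation of log2(FPKM + 1) was 0.939 to 0.975 among parental libraries, 0.977 to 0.986 among silenced libraries and 0.811 to 0.872 between the groups. These correlations are across genes, which are not independent replicates. The first principal component held 75.5% of the variance and separated the groups. The second held 12.9% and set parental replicate 1 apart from parental replicates 2 and 3. In that replicate 638 tested IDs lay at least 2-fold below both other parental libraries on the log2(FPKM + 1) scale. Depth is known only as an estimate relative to parental replicate 1, between 1 and 1.58.

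The targeted gene was strongly reduced in the strain labelled as silenced. Matched by its number and chromosome letter to the locus tag POX_c04478 on chromosome III, it fell from 135 ± 21.7 FPKM in the parental libraries to 17.6 ± 1.56 FPKM in the silenced libraries (SD, n = 3 each), so that 13% of the parental level remained. The log2 fold change was -2.87 ± 0.15 (SE), with an adjusted p of 0.00012 in limma. Each of the 3 silenced values lay below each parental value, and the exact two-sided permutation p was 0.1, the smallest that this design allows. Ranked by log2 fold change from the most negative, the target stood at 77 among the 9341 tested IDs.

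POX_c04479, which adjoins the target on one side, fell with it, from 93.4 ± 20.2 to 15.7 ± 1.2 FPKM (SD, n = 3), a log2 fold change of -2.48 ± 0.18 (SE; limma adjusted p = 0.00019). The ratio of POX_c04479 to POX_c04478 was 0.645 to 0.723 in the parental libraries and 0.783 to 0.961 in the silenced libraries. The following gene, POX_c04480, had 23.4 ± 1.95 and 23.2 ± 3.09 FPKM and did not pass the test. On the other side, POX_c04477 and POX_c04476 were listed at 0 in all 6 libraries, and POX_c04475 rose 1.93-fold, from 116 ± 30.5 to 224 ± 15.1 FPKM. Of the 13 other tested genes within 8 genes on either side, 2 rose, 3 fell and 8 did not pass the test. The 3 that fell were the consecutive genes POX_c04482, POX_c04483 and POX_c04484, with log2 fold changes of -0.68, -0.75 and -0.94, and POX_c04482 did not pass without silenced replicate 1 or 2. Because the labels state no strand-specific step and the counting program is not given, reads from overlapping transcripts of neighbours could not be told apart.

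**Figure D1:**
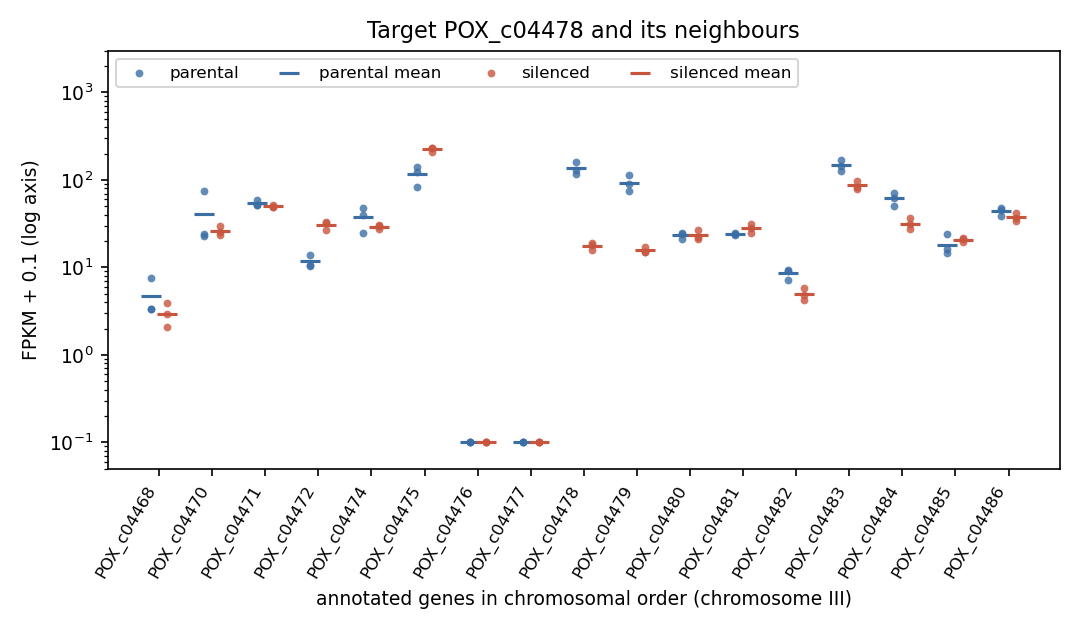
FPKM plus 0.1 (log axis) of the target and of 8 annotated genes on either side, in chromosomal order, with points for single libraries (blue parental, red silenced) and bars for the group means of 3 libraries. POX_c04478 and POX_c04479 are both lower in all 3 silenced libraries, while POX_c04480 beside them is at the same level in both groups within the spread.

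Changes extended well beyond the target. Of 9341 tested IDs, 5118 changed (54.8%), of which 2277 were higher and 2841 lower in the silenced libraries (limma, adjusted p under 0.05). With a log2 fold change of at least 1 required as well, 1376 were higher and 1438 lower. That balance turned with the setting, to 1599 higher and 1218 lower after median-of-ratios scaling and to 1130 higher and 998 lower with a pseudocount of 5. The groups did not overlap for 6155 tested IDs (65.9%), where chance gives 10%. The median log2 fold change over all tested IDs was -0.12 as deposited and -0.00032 after median-of-ratios scaling. That scaling brings the median close to 0 by construction, so the second value does not show whether the shift was real. Under that scaling 51.9% of the changed IDs were higher, against 44.5% as deposited.

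At the pseudocount of 1 used here, the 2 largest increases by the fixed rule belonged to adjacent genes, POX_g08982 and POX_g08983, on chromosome VII. POX_g08982 was listed at 0 in all 3 parental libraries and at 231, 205 and 229 FPKM in the silenced libraries (limma adjusted p = 1.3e-06). POX_g08983 rose 78.9-fold, from 32.1 ± 12.2 to 2534 ± 251 FPKM (SD, n = 3; adjusted p = 6.5e-05). The next gene, POX_g08984, rose 6.84-fold, from 8.57 ± 0.14 to 58.7 ± 9.66 FPKM. Of the 2 largest decreases by the rule, POX_e07319 on chromosome V fell from 280 ± 55.5 to 3.34 ± 1.96 FPKM (SD, n = 3; adjusted p = 0.00013). The other was an ID without a locus tag, which fell from 78.2 ± 36.4 to 0.467 ± 0.072 FPKM, and its log2 fold change of -5.65 ± 0.32 (SE) was -7.01 with a pseudocount of 0.1 and -3.84 with a pseudocount of 5. With a pseudocount of 0.1, IDs listed at 0 in one group ranked higher, so that POX_c04430 and POX_d06004 passed POX_g08983, and POX_b02370 and POX_g09289 passed both named decreases.

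**Figure D2:**
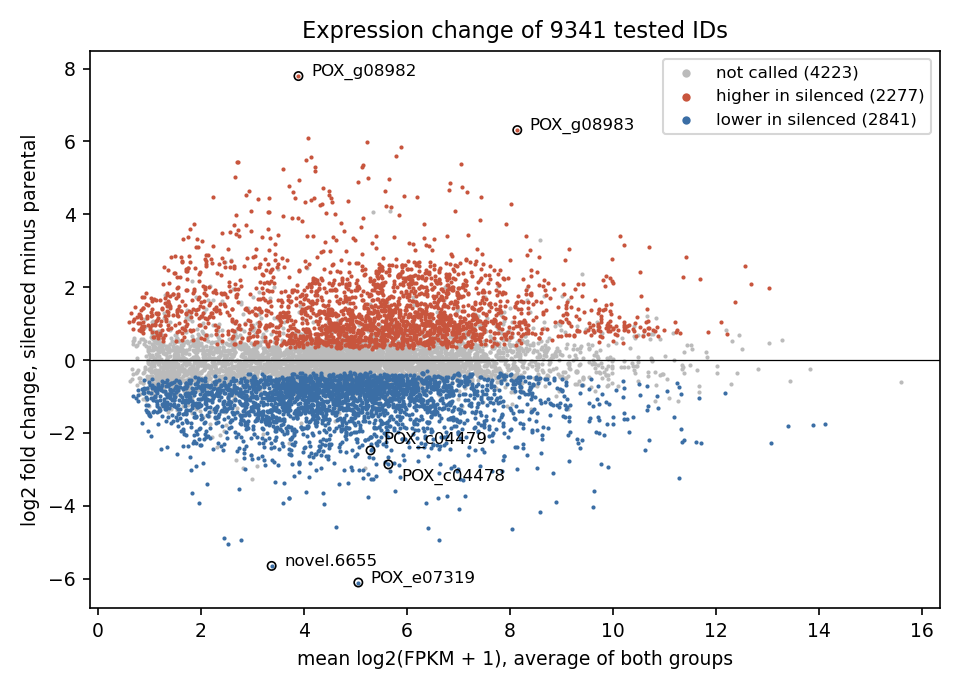
Log2 fold change (silenced minus parental) of each tested ID against its mean log2(FPKM + 1), with called IDs in red (2277 higher) and blue (2841 lower) and the others in grey. The target POX_c04478 and POX_c04479 lie together below the axis, and POX_g08982, POX_g08983, POX_e07319 are labelled near the extremes.

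The most abundant transcripts changed in both directions, with 4 of the 20 highest by mean FPKM higher and 4 lower in the silenced strain. POX_d04900 fell from 20395 ± 3221 to 5758 ± 502 FPKM and POX_a00825 from 18922 ± 499 to 3935 ± 343 FPKM (SD, n = 3), the highest and second highest parental means among the locus tags. Outside the 20 highest, POX_e07317, which lies 2 genes from POX_e07319, fell 9.56-fold, from 7829 ± 1448 to 819 ± 126 FPKM. POX_e06297, also outside them, fell 4.59-fold, from 5714 ± 237 to 1245 ± 54.8 FPKM. The IDs ranked 2 and 3 by mean FPKM, both without a locus tag, fell 3.36-fold and 3.44-fold. In the other direction, POX_a00166 rose 3.91-fold, from 4307 ± 1065 to 16848 ± 4512 FPKM. POX_c03646, POX_e06527 and POX_e06689 rose 4.66-fold, 3.25-fold and 2.61-fold, with log2 fold changes of 2.58, 2.08 and 1.60 that were 1.77, 1.23 and 0.99 without parental replicate 1. POX_e06527 and POX_e06689 did not pass without silenced replicate 1, 2 or 3 or with no filter, and POX_c03646 did not pass without silenced replicate 3. The ID with the highest mean over all libraries, also without a locus tag, had 64044 ± 24530 and 41242 ± 10963 FPKM and did not pass the test. The 10 most abundant IDs of each library took 15.9% to 19.0% of the summed FPKM in the parental libraries and 11% to 13.5% in the silenced libraries.

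Among the 100 IDs with the highest mean FPKM, 27 rose, 24 fell and 49 did not pass the test in limma. Of the 900 ranked below them down to rank 1000, 291 rose and 232 fell. This first count depended on single libraries, since it was 32 without silenced replicate 1 and 31 without silenced replicate 2, against 51 with all libraries.

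Some of the changed genes lay side by side along the chromosomes. Among 8404 tested genes placed in order on the 8 chromosomes, 32 runs of 4 or more neighbours changed together at least 2-fold on the log2(FPKM + 1) scale, 11 of them upward and 21 downward, and they held 160 genes. Shuffling the gene order 1000 times gave a mean of 7.09 runs and at most 16 (permutation p = 0.001, the smallest that these shuffles can give). Upward runs alone numbered at most 11 in the shuffles (permutation p = 0.002) and downward runs at most 10 (permutation p = 0.001). The log2 fold changes of adjacent genes correlated at 0.189 (Pearson, across genes), against at most 0.034 in the shuffles.

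The 2 longest runs both lay on chromosome III and both rose from low levels. The first comprised all 15 genes from POX_c04237 to POX_c04251, with a median log2 fold change of 4.05 and a range of 1.84 to 5.19. Within it, POX_c04237 rose 47.1-fold, from 2.38 ± 1.84 to 112 ± 20.8 FPKM, and POX_c04249 rose 36.7-fold, from 1.88 ± 1.93 to 69.0 ± 17.0 FPKM (SD, n = 3). Without parental replicate 3 these folds were 83.3 and 88.0. The second comprised 11 tested genes from POX_c04512 to POX_c04526, with a median log2 fold change of 3.09. There POX_c04517 rose 45.9-fold, from 1.81 ± 1.04 to 82.9 ± 17.0 FPKM, and POX_c04515 rose 6.90-fold, from 1.10 ± 0.13 to 7.59 ± 1.65 FPKM. In each of the 26 genes of both runs, all 3 silenced values exceeded all 3 parental values. Selecting called genes favours such separation, which held for 65.9% of all tested IDs, so it adds no separate support. Parental values were low in both runs, and with a pseudocount of 5 the medians of these runs were 2.79 and 1.63, the longest run held 10 genes and there were 11 runs in all, where shuffles gave at most 10.

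**Figure D3:**
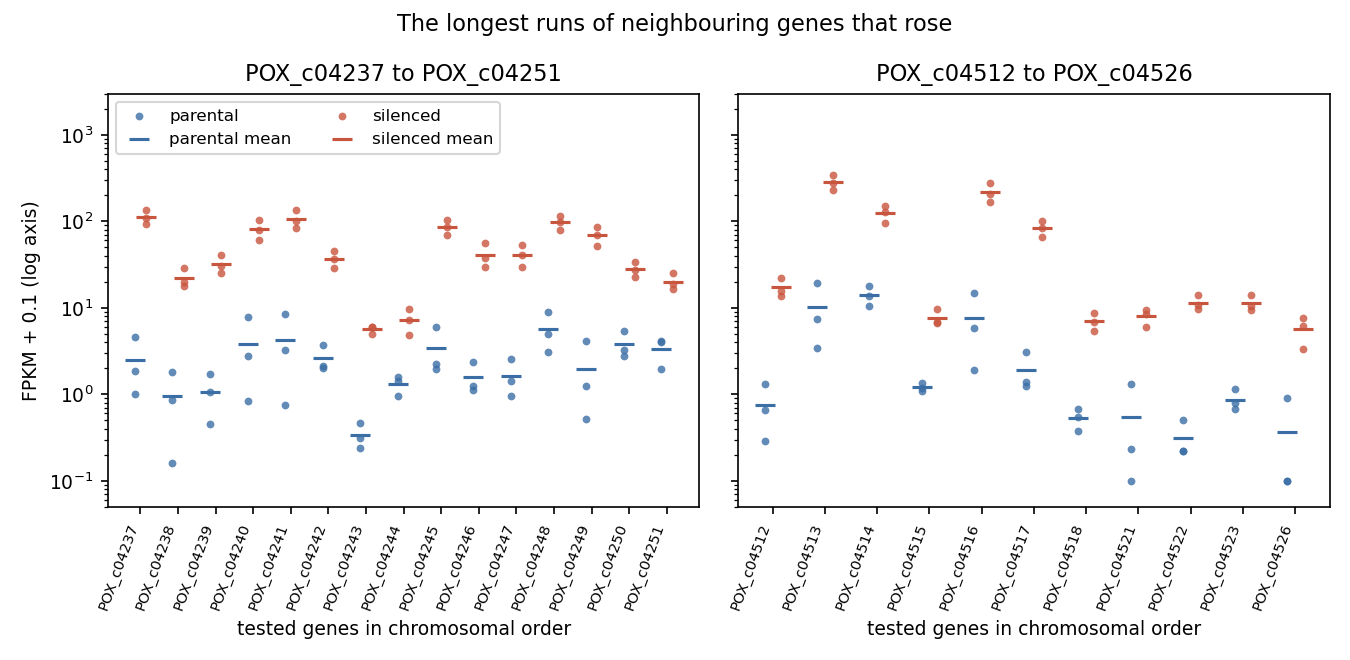
FPKM plus 0.1 (log axis) of the tested genes in the runs POX_c04237 to POX_c04251 (15 genes) and POX_c04512 to POX_c04526 (11 genes), in chromosomal order, with points for single libraries (blue parental, red silenced) and bars for group means of 3 libraries. In every gene shown the silenced libraries lie above the parental libraries, by factors that differ along each run. The genes were selected as called higher, which favours this separation.

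Downward runs were shorter than these and began from higher median levels. In the run from POX_c04729 to POX_c04732 on chromosome III, POX_c04729 fell 25-fold, from 1322 ± 76.5 to 52.9 ± 8.87 FPKM, and POX_c04730 fell 14.9-fold, from 375 ± 141 to 25.2 ± 0.97 FPKM (limma adjusted p = 5.8e-05 and 0.00017). The 5 genes from POX_b02072 to POX_b02076 on chromosome II fell with a median log2 fold change of -2.63, and POX_b02073 among them fell 8.60-fold, from 1371 ± 364 to 159 ± 39.1 FPKM. The 5 tested genes from POX_b02839 to POX_b02844, also on chromosome II, had a median of -2.83, and POX_b02842 fell 8.43-fold, from 361 ± 25.8 to 42.8 ± 3.26 FPKM. Without silenced replicate 1 there were 21 runs in both directions together, against 32 with all libraries. Shuffles there gave a mean of 4.4 and at most 12.

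A few genes were listed at 0 in every library of one group and at 5 FPKM or more in every library of the other. In this class, 8 IDs were listed at 0 in the parental libraries and 4 in the silenced libraries. Beside POX_g08982, the former included POX_c04430, at 46.2, 42.7 and 38.2 FPKM, and POX_d06004, at 62.4, 49.9 and 23.8 FPKM in silenced replicates 1, 2 and 3. The latter included POX_b02370, at 51.5, 18.4 and 24.9 FPKM, and POX_g09289, at 33.1, 7.94 and 10.5 FPKM in parental replicates 1, 2 and 3. No fold is given for these genes because a value of 0 has no known counting limit without the depth.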

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

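The number of changed IDs lay between 4562 and 6597 under the alternatives of pseudocount, filter, scaling, replicate block, variance trend and library weights, and between 3603 and 5576 when 1 library was left out. As a share of the tested IDs, 54.8% in the fit described, this ran from 39.2% without silenced replicate 2 to 70.6% with library weights, and fewer than the unchanged IDs were changed with no filter (49.3%), with the block (4667 of 9341) and without parental replicate 3 (48.3%), silenced replicate 1 (41.3%), 2 or 3 (46.5%). Requiring a log2 fold change of at least 1 left 2814. Every ID called both in the fit described and under an alternative had the same sign in both. The target gene passed the threshold in each alternative and ranged from -2.97 to -2.75 over the left-out libraries. Replicate numbers gave no clear sign of pairing over all tested IDs, since not every library correlated best with its own number, but pairing is not excluded. A replicate block gave 4667 changed IDs, 31 runs and 46 changed among the 100 most abundant. The number of runs of neighbouring genes was 11 with a pseudocount of 5 and 21 to 35 without 1 library, and the number changed among the 100 most abundant was 31 to 71 without 1 library. Fewer libraries and, for the pseudocount, compressed changes of low genes are part of how these settings are built. Among the values of single IDs under the alternatives, 683 kept their direction and side of the threshold and 11 no longer passed it: POX_e06527 and POX_e06689 in 4 each, POX_c04482 in 2 and POX_c03646 in 1. POX_c04480, which passed in none, changed sign in 6. No value was obtained where an ID failed the filter. This was so for POX_g08982, POX_c04430 and POX_d06004 without any 1 silenced library. It was also so for POX_b02370, POX_g09289 and the selected decrease without a locus tag, without any 1 parental library. Their calls were therefore not tested against leaving out a library of the group that expresses them. POX_c04244 and POX_c04515 had no value with the filter at a mean of 5 FPKM. The gene list tests were not run because no product names were given, nor were edgeR-type count tests because there are no counts. Without fragment numbers, counting error could not be separated from the spread between libraries.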

Other observations

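The tests of explanations given here were chosen after the results were seen, except the scaling and left-out library settings, which had been planned. IDs without a locus tag moved downward more than locus tags of like expression. Of 873 tested, 108 rose and 297 fell, and their median log2 fold change was -0.41, while 10000 random lists of locus tags matched on expression had medians between -0.32 and -0.036. With 1 library left out, 58 to 105 rose and 196 to 324 fell, and more fell than rose each time. These IDs took 12% to 16.2% of the summed FPKM in the parental libraries and 8.14% to 10.6% in the silenced libraries. Most of that share lay in a few very abundant IDs. The largest of them had group means of 64044 and 41242 FPKM and did not pass the test. The lower share therefore does not show a decrease of the whole class.

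The levels of the 2 long runs on chromosome III also differed between libraries of one group. The median FPKM of the run from POX_c04237 was 0.91, 1.78 and 3.87 in parental replicates 1, 2 and 3 and 29.5, 37.7 and 53.0 in silenced replicates 1, 2 and 3. The median of the run from POX_c04512 was 0.58, 0.80 and 1.22 in the same parental libraries and 9.48, 10.5 and 13.9 in the same silenced libraries. Both medians rose with the replicate number in both groups, so pairing by number is not excluded for these genes. Parental replicate 1 stood apart from the rest of its group, with 638 tested IDs at least 2-fold below both other parental libraries and 184 at least 2-fold above both, on the log2(FPKM + 1) scale. In the other 5 libraries these counts were 35 to 73 and 20 to 99. Abundant genes were among them: POX_c03646 had 810 FPKM there against 3727 and 5065, and POX_g08549 had 348 FPKM against 1516 and 2076. Both were called higher in the silenced libraries, at 14899 ± 1201 and 7268 ± 210 FPKM (SD, n = 3). Without parental replicate 1 their log2 fold changes went from 2.58 to 1.77 and from 2.82 to 2.03, and POX_c03646 did not pass the threshold without silenced replicate 3.

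POX_c04479 fell with the target beside it, which is a pattern to follow up because an effect of the silencing construct on the neighbour would bear on which gene the other changes follow. Silencing of like strength over all the surrounding genes was argued against by the 13 other tested genes within 8 genes on either side, whose median log2 fold change was -0.23 with an SD of 0.66. Coincidence among the many reduced genes stays open, because POX_c04479 was picked for its fall and the share of tested IDs that fell as far, 1.42%, then decides nothing. Reads of the target's transcript counted in POX_c04479 cannot be told apart from a real decrease. The group means are met by 0.660 of the target's FPKM plus a constant level of 4.09 FPKM. Such a match exists for any pair of genes, and only a negative constant level would have argued against shared reads. A shared control of both genes, an effect of the construct on both, and a weaker spread that includes the smaller decreases from POX_c04482 to POX_c04484 were not tested and stay open.

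For the runs of neighbouring genes that rose on chromosome III, extra copies of the segments would raise all members by the same factor. The largest and smallest changes within a run differed by at least 2.89 (log2, pseudocount 0.1), which was at least 5.30 standard errors. This argues against equal factors, but the extremes were picked from 15 and 11 members, so the standard errors overstate the certainty. Chance order of changed genes was argued against by the shuffles, of which none reached 15 genes (permutation p = 0.001, the smallest they can give, longest 7). Reads spilling from 1 abundant gene over a whole run were argued against by 3 members far below their run's peak. These lie between members at much higher levels. Spilling from several risen members into the low ones between them was not tested and stays open. No biological explanation was tested, and the silencing, the copper and any other difference between the strains stay open.

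Of the tested IDs 54.8% changed, and technical sources could contribute. Under median-of-ratios scaling 4709 of the 5118 calls remained with the same sign, and without parental replicate 1 4793 remained, which argues against scaling or that library as the whole cause. The 6 libraries can be split in 10 ways, too few for a share under 0.05, and the real split gave 5118 calls where the highest other gave 4. Every other split mixes parental and silenced libraries, so the difference between the groups widens its spread and lowers its calls. The 4 is therefore not the number expected by chance. Copper addition cannot be told apart from the silencing, because the labels give copper for 0 of the 3 parental libraries and all 3 silenced ones. Any other difference between the strains, including an effect of the construct itself, cannot be told apart from the silencing either. Whether both strains were cultured on the same day is not given in the labels.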
